A study of Lactococcus lactis subsp. lactis Il1403 with 10 samples.

How the data were processed

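Lactococcus lactis IL1403, a plasmid-free laboratory strain, was compared with a knockout of codY on DNA microarrays carrying PCR amplicons of its genes. CodY is a repressor of amino acid and peptide metabolism that binds DNA when branched-chain amino acids are plentiful. Per the labels, each of 5 slides took Cy3- and Cy5-labelled total RNA of both strains, with the knockout in Cy5 on slides 352, 57, 58 and 191 and in Cy3 on slide 351. Each slide carried every amplicon in 2 spots, which gave 10 spot sets. Per the series description, RNA came from 4 biological replicates of each strain, so a pair of slides shares a culture. Which slides these are is not given in the sources used here. P-values over slides are then too small by an amount that depends on that pair, and each of the 10 possible pairs was averaged in turn as an alternative. Growth conditions, scanner settings and normalisation are not given in the sources used here.

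The deposited table holds 1 signed log ratio per gene and spot set for 2109 genes, with no intensities, spot qualities or background. It is the value table of the series, made by the authors in a way that the table and labels do not state, and its log base, normalisation and direction are not stated either. The deposited values ran from -13.3 to 12.8 and were taken as log2 ratios: base 10 would need impossible ratios, and as natural logs 3 values would lie outside the range of a 16-bit scanner. If the base were e, each fold given here would be larger and no test would change. The medians of the 10 columns, in the order first and second spot set, were 0.016 and -0.00062 on slide 352, -0.036 and -0.023 on slide 57, -0.0029 and -0.017 on slide 58, 0.019 and 0.0045 on slide 191, and -0.0017 and 0.0024 on slide 351. The columns thus were centred near 0 as deposited, by a method that is not known here.

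Slide 351 correlated positively with each of the 4 slides of opposite dye orientation, so its values were taken as already turned by the submitters, by a rule fixed before the data were examined. All signs were read as knockout over wild type. This direction is likely and not stated: its basis is the negative mean of codY itself on slides 352, 57, 58 and 351. Slide 191 adds no basis, since its codY spots differed in sign, at 0.07 and -0.25; its values correlated positively with those of the other 4 slides. If the ratio ran the other way, every direction given here would be reversed.

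The 2 spot sets of a slide were averaged and the slide was the unit of replication. Mean log2 ratios were tested against 0 with limma version 3.58.1 (lmFit with an intercept, then eBayes) in R version 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A minimum of 3 slides per gene was set, which all 2109 genes met. The exact test for codY flipped the signs of the slides (32 flips, two-sided). A total of 21 gene lists fixed before the data were examined were tested with limma's camera method on z scores with its preset correlation of 0.01. The test was repeated with a correlation between genes estimated from the residuals of the 4 slides with nearly all genes. This repeat also took p from a t distribution with 4 degrees of freedom, far fewer than in the main test. The estimated correlation was 0 for the branched-chain, glutamate and aspartate lists, so their rise in unadjusted p came from the degrees of freedom alone. A further repeat used fry on the 2082 genes complete on those 4 slides. Counts of list members are given adjusted over all genes and adjusted over the list alone.

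Genes were named by a rule fixed beforehand: codY, the 10 genes with the largest change each way among those past the threshold with one sign on every slide measured, up to 4 called members of each list or, where none was called, the 2 with the smallest p, and the annotated neighbours of codY. Other genes named were chosen after their values were seen, as stated where they appear. Gene symbols are those of the deposited table. No genome of strain IL1403 was used here. The gene table of assembly ASM317683v1 (another strain, with 2659 genes) served only to find which genes lie beside codY; 347 of the 2109 symbols had a match in it. The planned search for a CodY binding sequence upstream of the genes was therefore not run.

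The fit was tested on simulated data with the spread of these slides after moderation by eBayes, in 20 simulations of 2109 genes with 200 changed. Of genes changed by a log2 ratio of 1, 83.35% were recovered, and of those changed by 2, 97.45%, with 5.0% false calls. Simulated slides and genes were independent with normal noise, whereas a pair of the real slides shares a culture. With 200 planted genes the adjusted threshold is also easier to pass than with 5 calls. These rates check the code and do not give the power or false calls of this design. Of 2000 random lists of 15 genes, drawn from all genes of the real data with called ones included, 3.3% had an unadjusted p under 0.05. Genes drawn at random lack the correlation within real lists, estimated at 0.30 for oligopeptide uptake and 0.52 for purine synthesis. The rate of 3.3% therefore does not carry over to such lists. Alternatives tried were a dye term, centring of spot sets, scaling of slides to one spread, each spot set alone, the slide as a random block, other minimum numbers of slides, eBayes with trend and robust settings, no moderation, leaving out each slide, the opposite sign for slide 351, pairs of slides as 1 replicate and other thresholds. The dye term sets slide 351 against the other slides, so that fit gives slide 351 as much weight as the rest together. Averages over spot pairs that agree within a log2 ratio of 1, and a fit without slides 57 and 58, were added after seeing the data. The number of arrays limits the precision of every value, and with no intensities the distance of a spot from background is unknown.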

Results

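Log ratios of transcript levels between the codY knockout and its wild-type parent were collected for 2109 genes of L. lactis IL1403 on 5 two-colour slides, 4 with the knockout in Cy5 and 1 with the knockout in Cy3. Slides 352, 57, 58 and 351 had a value for 2104, 2107, 2094 and 2103 genes, and slide 191 for 853. In all, 844 genes were measured on 5 slides, 1246 on 4 and 19 on 3. The design asks which genes change when CodY is lost, and the series title adds which DNA sequence marks them. The second question needs the genome of this strain, which was not used here.

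Duplicate spots on one slide correlated across genes with Pearson's r of 0.33 on slide 352, 0.41 on slide 57, 0.46 on slide 58, 0.79 on slide 191 and 0.31 on slide 351, a mean of 0.46 ± 0.19 (SD, n = 5 slides). The value for slide 191 rests on 647 genes with both spots, against 1990 to 2040 on the others. Over the genes that slide 191 measured, r on the other slides was 0.50 to 0.57. Between 4.17% and 12.1% of spot pairs differed by more than 1 on the log2 scale. Slides correlated less with each other than their own spots did on average, with a mean r of 0.19 ± 0.12 (SD, n = 10 pairs of slides that share members). Pairs with slide 191 rest on the fewer genes it measured, so pairs were ranked over the 844 genes on all 5 slides. There slides 57 and 58 were highest with r = 0.51, followed by slides 352 and 351 with 0.42 and slides 191 and 351 with 0.40, and slides 57 and 191 were lowest with 0.14. These correlations run across genes, which are not independent replicates.

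**Figure D1:**
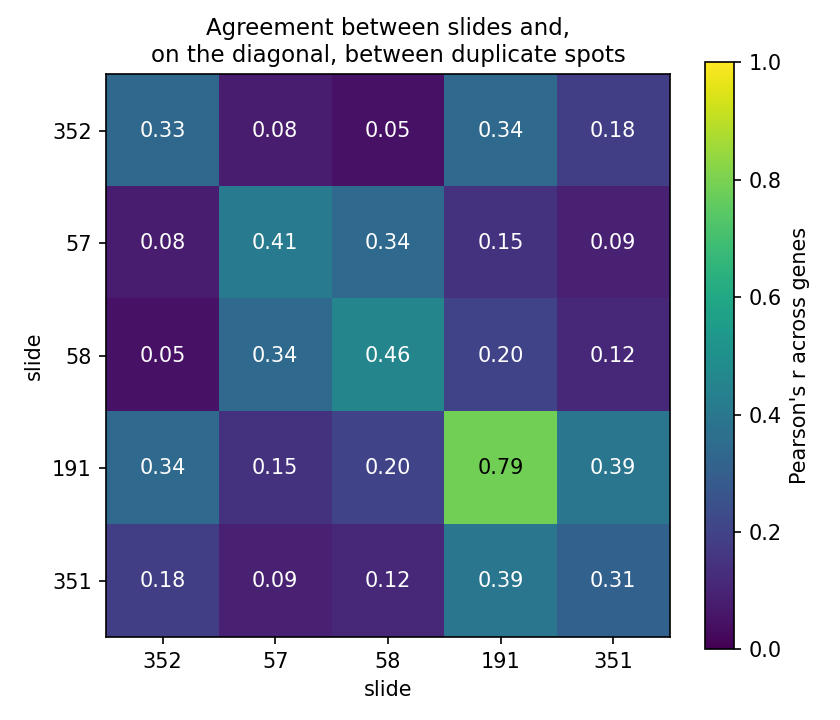
Pearson's r across genes between each pair of the 5 slides (spot sets averaged) and, on the diagonal, between the duplicate spots of one slide; both axes give the slide number and the colour gives r from 0 to 1. Duplicate spots of slide 191 stand at 0.79. All values for slide 191, on and off the diagonal, cover fewer genes than the others.

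The deleted gene, codY, had one sign on 5 of 5 slides. Since the direction of the ratios was read from this sign, its being lower in the knockout is an assumption and not a finding, and the values show only its size and spread. Its log2 ratios were -0.54 on slide 352, -1.61 on slide 57, -1.87 on slide 58, -0.09 on slide 191 and -1.06 on slide 351. The mean was -1.03 ± 0.74 (SD, n = 5), a 2.05-fold lower level. On slide 191 its spots stood at 0.07 and -0.25. The difference from 0 did not pass the threshold over all genes (limma adjusted p = 0.378), and the exact sign-flip test gave p = 0.0625, the smallest that 5 slides allow. With the 10 spot sets fitted and the slide as a random block, the adjusted p was 0.036. That fit gives every gene the same correlation between duplicate spots, 0.435, and so partly counts spots as replicates. The codY spots stood at -1.66 and -1.56 on slide 57 and both at -1.87 on slide 58. The labels do not say which part of codY was deleted or where its amplicon lies, so the remaining signal does not measure how complete the deletion was. The neighbouring gene gatC, coding for a subunit of the amidotransferase that makes Gln-tRNA, had a mean of -0.0059 ± 0.22 (SD, n = 5, adjusted p = 0.983).

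A set of 5 genes was higher in the knockout at the threshold over all genes, each on 5 of 5 slides, and 0 were lower. They were gltD, coding for the small subunit of glutamate synthase, at a log2 ratio of 2.62 ± 0.81 (SD, n = 5; 6.13-fold, limma adjusted p = 0.045); ilvD, coding for dihydroxy-acid dehydratase of isoleucine and valine synthesis, at 2.44 ± 0.65 (adjusted p = 0.032); ymdC at 2.41 ± 0.52 (adjusted p = 0.031); pepO, coding for an endopeptidase, at 2.30 ± 0.56 (adjusted p = 0.031); and hisA, coding for an isomerase of histidine synthesis, at 2.22 ± 0.69 (adjusted p = 0.045). The next 8 genes by p, with adjusted p from 0.052 to 0.087 and chosen after their values were seen, were also all higher on 5 of 5 slides. They were oppA, oppD, oppF and optS of oligopeptide uptake, ilvN, ctrA, amtB and icd.

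At an unadjusted p under 0.05, limma gave 105 genes higher and 73 lower, where 105.45 in total would arise by chance. Of the 844 genes on 5 slides, 80 were higher on every slide and 42 lower on every slide. Chance gives 6.25% of genes for both directions together. That rate takes the 5 slides as independent, whereas a pair of them shares a culture. The count of 5 rests on every slide: it was 0 without slide 352, 0 without slide 57, 1 without slide 58, 3 without slide 191 and 1 without slide 351. Averaging slides 57 and 58, the pair with the highest correlation over common genes, as 1 biological replicate left 0 genes higher and 0 lower, so 0 of the 5 were kept. The count of genes higher was also 0 with slides scaled to one spread, without moderation or with trend and robust settings. With the slide as a random block, which partly counts duplicate spots as replicates, 27 genes were higher and 3 lower.

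**Figure D2:**
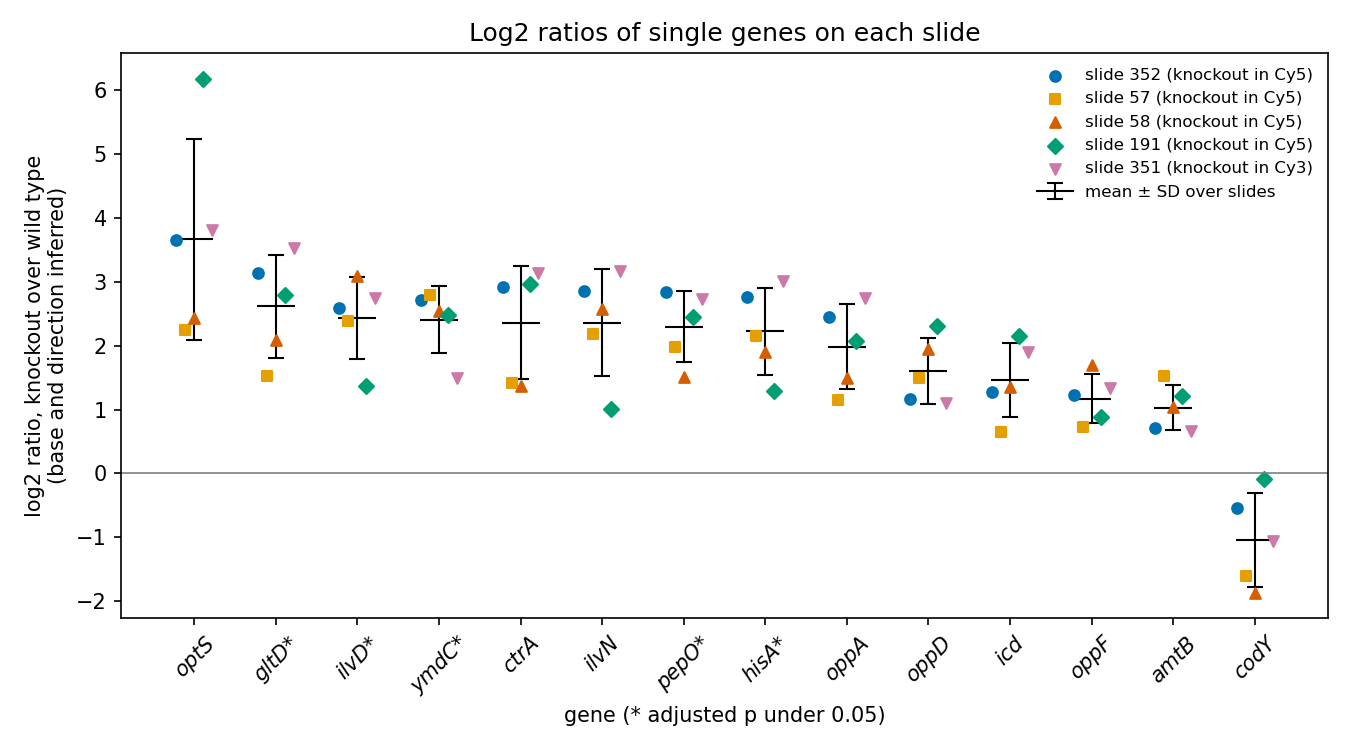
Log2 ratio of knockout over wild type (vertical axis, base and direction inferred) for codY and the 13 genes with adjusted p under 0.10, each point a slide (mean of its spots) and each bar the mean ± SD over 5 slides; an asterisk marks adjusted p under 0.05. All 13 genes lie above 0 on each slide, and codY lies below 0 on each slide, between -1.87 and -0.09.

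Oligopeptide uptake genes were shifted upward as a group. The median over the 12 measured genes of the Opp, Opt and DtpT systems was 1.19, and the list median was above 0 on 5 of 5 slides, from 0.58 on slide 57 to 2.28 on slide 191 (camera adjusted p = 4.9e-10). With an estimated correlation the adjusted p was 0.141. Adjusted over the list alone, 8 genes were higher and 0 lower, and over all genes 0 passed. The 8 were oppA, oppB, oppC, oppD, oppF, optA, optC and optS. The peptide-binding protein gene oppA stood at 1.99 ± 0.66 (SD, n = 5; adjusted p over all genes 0.052) and the ATPase gene oppD at 1.61 ± 0.52 (0.052). Another binding protein gene, optS, had the largest mean of the 8, at 3.67 ± 1.57 (0.087). The di- and tripeptide transporter gene dtpT stood at -0.02 ± 0.37. The call of the list ended when slide 351 was given the opposite sign (median 0.55, adjusted p = 0.064). A fall was built in there, since the list median of slide 351 was 1.28 before the turn. Without slide 351 the list stayed past the threshold (median 1.11, camera adjusted p = 3.5e-07).

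Genes of branched-chain amino acid synthesis and transamination had a median of 0.81 over 11 measured genes (camera adjusted p = 1.1e-05). The list median was above 0 on 5 of 5 slides, from 0.05 on slide 351, the slide with swapped dyes, to 1.19 on slide 191. Slide 191 measured 6 of the 11 genes. Over these 6 the medians were 0.87 on slide 352, 1.41 on slide 57, 2.58 on slide 58 and 0.78 on slide 351. With an estimated correlation, here 0, and fewer degrees of freedom, the adjusted p was 0.089. Of these, ilvD passed over all genes, and 4 were higher adjusted over the list alone: ilvD, ilvN at 2.36 ± 0.84 (SD, n = 5; adjusted p over all genes 0.057), aldB at 0.82 ± 0.34 and bcaT at 0.75 ± 0.37. The product of ilvN is the small subunit of acetolactate synthase, that of aldB is acetolactate decarboxylase and that of bcaT is the branched-chain aminotransferase. The other 7 did not pass either way. The list median was 0.45 with a dye term and 1.23 among genes measured on all 5 slides, and the list stayed past the threshold in both fits (adjusted p = 0.00084 and 7.3e-06). Of the 7, leuD spread widest, from -2.51 on slide 351 to 6.51 on slide 352. The list median of 0.81 is the mean of leuD, which was above 0 on 1 of the 4 slides that measured it.

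Histidine synthesis genes had a median of 0.67 over 10 genes, above 0 on 5 of 5 slides (camera adjusted p = 0.00011). Slide 191 measured 5 of the 10, and over these 5 the median on slide 57 was -0.06. The other slides stayed above 0 there, from 0.54 on slide 58 to 2.31 on slide 351. With an estimated correlation the adjusted p was 0.409. Over all genes, hisA passed. Adjusted over the list alone, hisA, hisB at 1.75 ± 1.21 (SD, n = 5) and hisH at 0.73 ± 0.19 (SD, n = 4) were higher. With slide 351 given the opposite sign the list had a median of 0.18 and an adjusted p of 0.538, and with the second spot set its median was 0.39. Without slide 351 the list stayed past the threshold (median 0.56, camera adjusted p = 0.0049).

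Genes of glutamate and glutamine synthesis and uptake, listed with gadB, gadC and the branch from citrate to 2-oxoglutarate, had a median of 0.24 over 14 genes. It was above 0 on 5 of 5 slides (camera adjusted p = 0.0020). With an estimated correlation, here 0, and fewer degrees of freedom, the adjusted p was 0.141. Over all genes gltD passed, and gltD, the isocitrate dehydrogenase gene icd at 1.46 ± 0.59 and the ammonium transporter gene amtB at 1.03 ± 0.36 (SD, n = 5 each) were higher adjusted over the list alone. The product of gltD makes glutamate, that of icd makes 2-oxoglutarate and that of amtB takes up ammonium. The list's median moved between fits: it was 0.76 among genes measured on all 5 slides, 0.12 with slide 351 given the opposite sign (adjusted p = 0.130) and, in the alternatives added after seeing the data, 0.14 with agreeing spot pairs and 0.07 without slides 57 and 58. Without slide 351 the list stayed past the threshold (median 0.20, camera adjusted p = 0.0049).

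The aspartate family, genes of asparagine, lysine and threonine synthesis, had a median of 0.44 over 12 genes, above 0 on 5 of 5 slides (camera adjusted p = 3.4e-05). With an estimated correlation, here 0, and fewer degrees of freedom, the adjusted p was 0.089. Over all genes 0 passed, and 5 were higher adjusted over the list alone. These were the asparagine synthetase gene asnB at 2.07 ± 1.003, the threonine synthase gene thrC at 0.97 ± 0.48, lysA at 0.95 ± 0.48, thrA at 0.91 ± 0.78 and dapB at 0.67 ± 0.36 (SD, n = 5 each). In fry, which asks whether a list's genes move one way on balance, this list and those of branched-chain amino acids and of glutamate were past the threshold, each with adjusted p = 0.0124, and the remaining 18 were not.

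The purine list went the other way, with a median of -0.55 over 19 genes of purine synthesis and salvage (camera adjusted p = 0.00028; adjusted p = 0.593 with an estimated correlation), and 0 members passed over all genes or over the list alone. The list median was -1.40 on slide 57 and -1.31 on slide 58, against 0.06 on slide 352, -0.15 on slide 191 and -0.04 on slide 351. Slide 191 measured 8 of the 19 genes, and over these the medians were -0.34 on slide 57 and -0.87 on slide 58. Without slide 58 the median was -0.31, and among genes measured on all 5 slides the call ended (median -0.21, adjusted p = 0.060). In a fit without slides 57 and 58, added after seeing the data, it was 0.05 (adjusted p = 0.971). The 2 genes with the smallest p were purB at -0.59 ± 0.47 (SD, n = 5, adjusted p = 0.525) and purL at -2.25 ± 1.82 (SD, n = 4, adjusted p = 0.528).

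Calls of 2 further lists depended on single slides and on the settings of the fit. Pyrimidine synthesis genes had a median of 0.19 over 13 genes (adjusted p = 0.0096; adjusted p = 0.593 with an estimated correlation), with 0 members passing over all genes or the list alone. The list median was 0.45 on slide 57 and 0.50 on slide 58 and between -0.13 and 0.014 on the others, and the call ended without slide 57 (median 0.10, adjusted p = 0.051) and without slide 58 (median 0.14, adjusted p = 0.213). Without both, in the fit added after seeing the data, the median was 0.018 (adjusted p = 0.991). Its smallest p belonged to the uridine phosphorylase gene udp at 1.26 ± 1.30 and the regulator gene pyrR at 0.35 ± 0.31 (SD, n = 5 each; adjusted p = 0.565 each). Heat shock chaperone and Clp protease genes had a median of 0.29 over 14 genes (adjusted p = 0.0143; adjusted p = 0.593 with an estimated correlation), also with 0 members passing. The list median was 0.97 on slide 58 and at most 0.11 on the others, and the call ended without slide 58 (median 0.14, adjusted p = 0.236) and without slides 57 and 58 (median 0.06, adjusted p = 0.561). The chaperone call also ended with the second spot set (median 0.26, adjusted p = 0.118), without moderation (median 0.29, adjusted p = 0.052), with slide 351 given the opposite sign (median 0.20, adjusted p = 0.058) and with agreeing spot pairs (median 0.26, adjusted p = 0.052). Without slide 351 the chaperone call held (median 0.31, camera adjusted p = 0.016). The heat shock repressor gene hrcA stood at 0.68 ± 0.49 and clpB at 0.53 ± 0.49 (SD, n = 4 each). With a dye term, which gives slide 351 as much weight as the rest together, both calls ended while the medians stayed above 0. They were 0.16 for pyrimidine (camera adjusted p = 0.187) and 0.19 for chaperone genes (camera adjusted p = 0.136). Among genes measured on all 5 slides, a smaller set, both calls also ended with medians of 0.18 for pyrimidine (adjusted p = 0.144) and 0.26 for chaperone genes (adjusted p = 0.479).

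**Figure D3:**
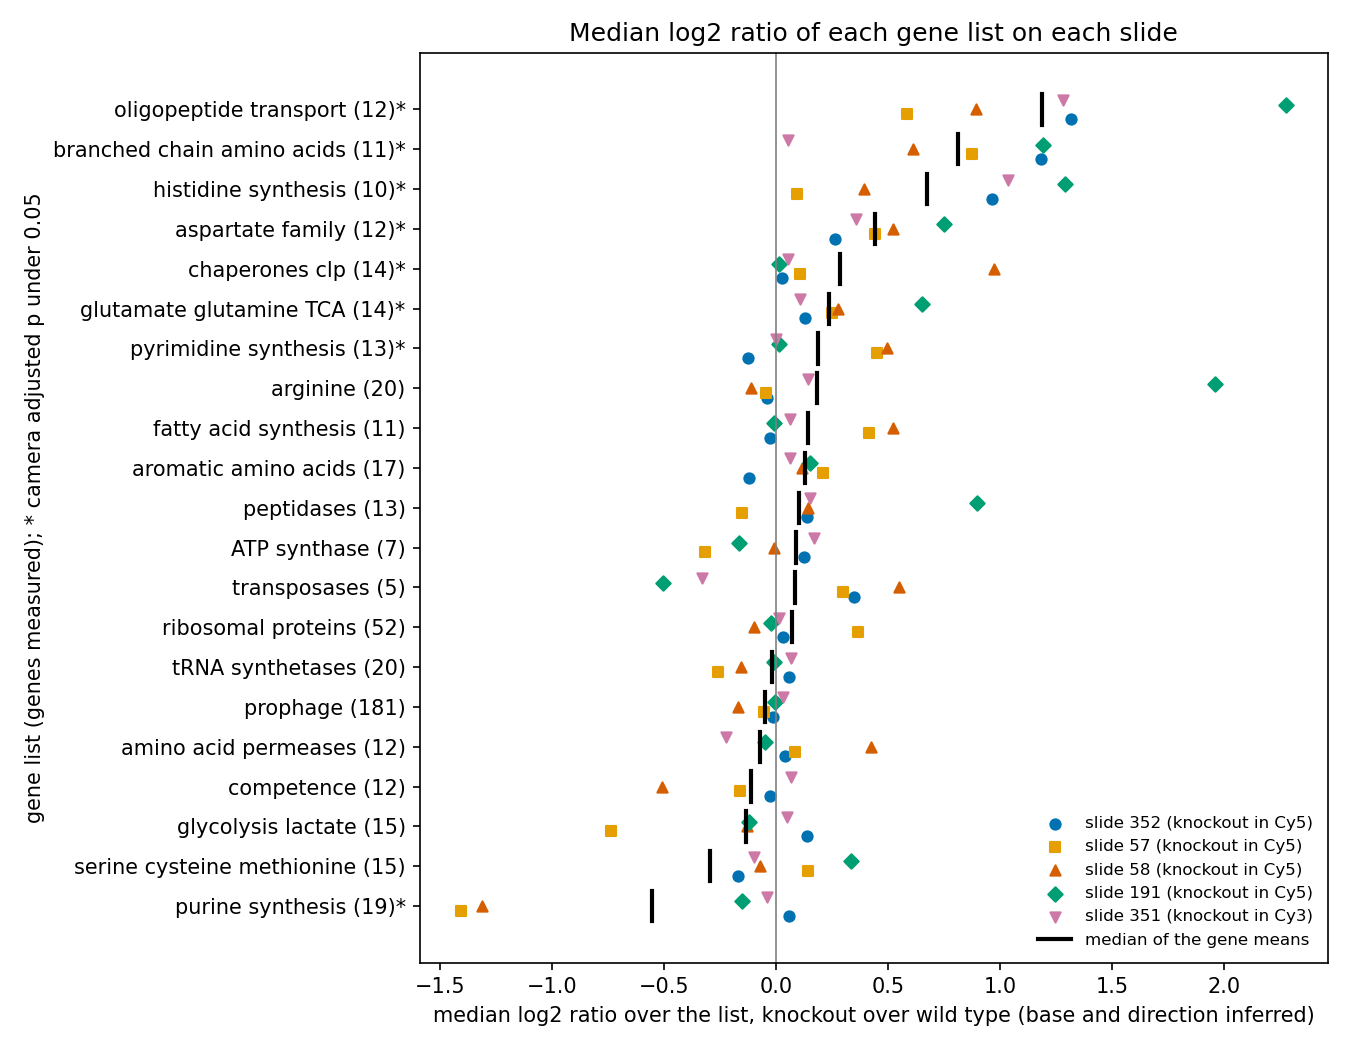
Median log2 ratio of knockout over wild type (horizontal axis, base and direction inferred) of the 21 gene lists on each slide (points) and the median of the gene means (black bar), with the number of genes measured in brackets and an asterisk for camera adjusted p under 0.05 with the preset correlation. The bar of oligopeptide uptake stands at 1.19 and that of purine synthesis at -0.55, where slides 57 and 58 stand at -1.40 and -1.31; slide 191 measured only part of most lists, so its points cover fewer genes.

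Several lists of amino acid metabolism did not shift as a whole but held members that passed over the list alone. The 13 intracellular peptidase genes had a median of 0.10 (camera adjusted p = 0.245), and of them pepO passed over all genes. Without slide 57 the list had a median of 0.18 and an adjusted p of 0.046. Without slides 57 and 58, in the fit added after seeing the data, these were 0.22 and 0.021. The 12 genes of the amino acid permease list had a median of -0.07 but a mean of 0.24 and a mean z score of 0.30 (adjusted p = 0.548). They were listed by symbol, busAA, busAB and acpA among them, and were not each checked to code for such a permease. Adjusted over the list alone, ctrA at 2.36 ± 0.89, ydgC at 0.62 ± 0.34 and ydgB at 0.38 ± 0.17 were higher and yshA at -0.89 ± 0.57 was lower (SD, n = 5 each). In the list of 15 serine, cysteine and methionine genes, with a median of -0.29 (adjusted p = 0.235), the serine synthesis genes serA at 1.95 ± 1.25, serC at 1.24 ± 0.70 and serB at 0.96 ± 0.49 (SD, n = 5 each) were higher and ytjE at -0.75 ± 0.29 (SD, n = 4) was lower, adjusted over the list alone.

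The 20 genes of arginine synthesis and the arginine deiminase pathway had a median of 0.18 (adjusted p = 0.449), with 1.96 on slide 191 and at most 0.14 on the others. Slide 191 measured 6 of the 20, and over these 6 the medians were 0.84 on slide 352, 0.15 on slide 57, 0.21 on slide 58 and 0.63 on slide 351. Among genes measured on all 5 slides the list had a median of 0.58 (adjusted p = 0.051). Leaving out each slide gave medians from 0.016 without slide 57 to 0.21 without slide 352. Adjusted over the list alone, the carbamate kinase genes arcC2 at 1.05 ± 0.54 (SD, n = 5) and arcC1 at 0.95 ± 0.52 (SD, n = 4) were higher, and the argininosuccinate lyase gene argH at -0.99 ± 0.49 (SD, n = 4) was lower. Aromatic amino acid synthesis had a median of 0.13 over 17 genes (adjusted p = 0.352), with araT at 0.34 ± 0.18 and aroB at 0.48 ± 0.63 (SD, n = 5 each), and 0 members passed. Its median ran from 0.019 without slide 57 to 0.16 without slide 191.

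The remaining 8 lists held 0 genes that passed over all genes or over the list alone. Medians were 0.07 for 52 ribosomal protein genes (camera adjusted p = 0.280), -0.02 for 20 aminoacyl-tRNA synthetase genes (0.551), -0.13 for 15 glycolysis and lactate genes (0.235), 0.09 for 7 ATP synthase genes (0.673), 0.14 for 11 fatty acid synthesis genes (0.072), -0.11 for 12 late competence genes (0.360), and -0.05 for 181 prophage genes (0.072). The 5 transposase genes had a median of 0.09, a mean of -0.01 and a mean z score of 0.35 (0.595). Slide 191 had no value for the competence genes. Leaving out 1 slide brought some of these past the threshold: without slide 352 fatty acid synthesis (0.024), prophage (0.038) and glycolysis genes (0.029), without slide 58 ribosomal protein genes (0.026), without slide 191 fatty acid synthesis (0.044) and without slide 351 prophage genes (0.0098). With the slide as a random block, fatty acid synthesis also passed (0.036).

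Single genes with the smallest p in these lists did not pass. Among them were the asparaginyl-tRNA synthetase gene asnS at 0.99 ± 1.10 (SD, n = 5, adjusted p = 0.565), the glucokinase gene glk at 0.56 ± 0.58 (SD, n = 5, 0.565), the prophage gene pi120 at 0.56 ± 0.16 (SD, n = 4, 0.293) and the acetyl-CoA carboxylase gene accB at 0.46 ± 0.43 (SD, n = 5, 0.565).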

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

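The 3 tests on the purine list were chosen only after its values on each slide were seen. Of 69 values tested for a slide far from the others (single genes, list medians and slide measures), 7 had one, where chance gives about 1 in 20, or 3.45.

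The 5 called genes and the 8 shifted lists were set against the other sign patterns of the 5 slides, counting a pattern and its mirror once. As many called genes came from 1 of the 16 patterns, the real one with 5, and the highest of the others was 0. As many lists came from 3 of the 16 patterns, the real one with 8 and the highest other with 9. That highest pattern turned the signs of slides 57 and 58 together. A total of 16 patterns is too few for a share under 0.05.

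Slide 191 had values for 853 genes, against 2094 to 2107 on the others. All 13 genes with adjusted p under 0.10 were among these, although they make up 40.4% of the genes. An extra slide giving more power was argued against: in a fit without slide 191, 13 of the 13 genes with the smallest p still belonged to them, where 5.25 were expected and the binomial limit was 9. Better measurement of these genes on every slide may account for the pattern. Duplicate spots correlated better over them on 4 of the 4 other slides. The values of r were 0.50 against 0.22 on slide 352, 0.57 against 0.28 on slide 57, 0.53 against 0.40 on slide 58 and 0.56 against 0.20 on slide 351. Such an r also rises with the spread of real changes, and these genes include all 13. It therefore cannot tell better measurement from larger changes. Whether slide 191 was filtered on brightness stays open, since the table holds no intensities, and no biological explanation was tested.

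The purine list stood at -1.40 and -1.31 on slides 57 and 58 and between -0.15 and 0.06 on the rest. Dye orientation alone would not part slides 57 and 58 from slides 352 and 191, which share their dyes. With a dye term, which gives slide 351 as much weight as the rest together, the list median was -0.41 (camera adjusted p = 0.030). A knockout effect of about the overall -0.55 on every slide stays open. The genes of the list move together (estimated correlation 0.517), so that their number overstates the precision of a slide. That correlation was estimated on slides that include 57 and 58, so the split itself raises it. Before widening, the lower bootstrap bounds of the list median were -0.13 on slide 352, -0.41 on slide 191 and -0.23 on slide 351. With bootstrap intervals widened for that correlation, the lower bound of the list median was -0.545 on slide 352 and -0.711 on slide 191, which have the dyes of slides 57 and 58, and -0.654 on slide 351, so slide 352 alone lay above -0.55, narrowly. A culture, day or slide batch shared by slides 57 and 58 may account for it: over 836 genes outside the list, these slides correlated with Spearman's rho of 0.492, and the highest other pair reached 0.299. An effect of the knockout that appears only in some cultures stays open and was not tested.

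On slide 351, ymdC stood at 1.501, against 2.48 to 2.80 on the other slides. On slide 191, arcC2 stood at 1.97, against 0.63 to 0.99. The peptidase list had a median of 0.897 on slide 191, against -0.15 to 0.15; over the 9 genes that slide 191 measured, the others ran from -0.17 to 0.24. The arginine list had a median of 1.96 on slide 191, against -0.11 to 0.14; over the 6 genes that slide 191 measured, the others ran from 0.15 to 0.84. The ribosomal protein list had a median of 0.367 on slide 57, against -0.10 to 0.03. The chaperone list had a median of 0.972 on slide 58, against 0.01 to 0.11.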

How the results depend on the processing

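The fits on spot pairs that agree and without slides 57 and 58 were chosen after seeing the data; the rest were planned. The genes higher in the knockout, 5 as reported, numbered 3 with a dye term, 0 with slides scaled to one spread, 2 with the first spot set, 27 with the slide as a random block, 14 among the 844 genes on all 5 slides (fewer genes tested), 0 with trend and robust settings, 0 without moderation, 0 with slide 351 given the opposite sign, 10 with spot pairs that agree within 1 (949 pairs left out), 0 at adjusted p under 0.01 and 0 to 9 over the 10 pairings of slides, with 0 for slides 57 and 58 and 9 for slides 57 and 191. Leaving out each slide gave 0 to 3. The random block and the genes on all 5 slides kept all 5 genes, the agreeing spot pairs kept all 5, the dye term kept 1, and the fit without slides 57 and 58 called 5 genes, 2 of them shared. The genes lower numbered 3 with the random block (codY, yxbF and ybiE) and 0 in the other fits. The mean of codY stayed below 0 in every fit, from -1.27 to -0.56, and passed the threshold with the random block alone (-1.03, adjusted p = 0.036, against 0.165 to 0.774 in the other fits). Lists past the threshold, 8 as reported, numbered 5 among genes on all 5 slides and 5 with slide 351 given the opposite sign (4 of the 8, and prophage). Turning slide 351 pulls towards 0 each mean whose sign that slide shares, so falls in that fit were partly built in. They numbered 0 with an estimated correlation, a fit that also had fewer degrees of freedom, and 3 with fry. Leaving out each slide gave 7 to 11. With the slide as a random block, all 8 and the fatty acid synthesis list passed. Apart from fewer genes or slides, the cause was not tested. The minimum of 2 slides removed no gene and tests nothing.

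No reversed value had passed the threshold except that of the purine list, -0.55 as reported. The purine list went to 0.049 without slides 57 and 58, where also the atpG log2 ratio went to -0.022 and the lists of tRNA synthetases to 0.052, glycolysis to 0.046, fatty acid synthesis to -0.032, competence to 0.047, prophage to 0.012 and transposases to -0.163. The tRNA synthetase list went to 0.0085 with scaled slides, the aroB log2 ratio to -0.069 with the first spot set, and gatC to 0.173 and the ATP synthase list to -0.055 with the second. The permease list went to 0.035 among genes on all 5 slides, 0.138 with slide 351 opposite (where the tra983L log2 ratio went to 0.494), 0.233 on the 4 slides used for fry (where the ATP synthase list went to -0.0014) and 0.0028 with agreeing spot pairs (where competence went to 0.0024). The highest gatC over the pairings was 0.040. Leaving out each slide gave ranges that cross 0: -0.043 to 0.212 for transposases, -0.018 to 0.133 for ribosomal proteins, -0.150 to 0.126 for permeases, -0.0014 to 0.099 for ATP synthase and -0.052 to 0.085 for the gatC log2 ratio. Each named gene or list was counted once per alternative. Direction and call, or lack of a call, were kept in 791 comparisons of genes and 357 of lists. The call was lost in 60 and 30 and gained in 31 and 10. Only the 5 called genes and 8 called lists could lose a call, and most named ones were uncalled throughout. These totals therefore do not measure how stable the calls were. All 5 genes kept the call with centred spot sets, the random block, genes on all 5 slides and agreeing spot pairs. With scaled slides, trend and robust settings, no moderation or slide 351 opposite, 0 kept it. The search for a CodY binding sequence, with its alternatives, was not run. Signal over background is unknown, so the limit it sets is too.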

Other observations

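The genes of this part were chosen after their values were seen. The aconitase gene citB, next to icd in the path from citrate to 2-oxoglutarate, stood at 3.18 on slide 352, 3.59 on slide 191 and 3.38 on slide 351, but at -0.74 on slide 57 and 0.29 on slide 58, with a mean of 1.94 ± 2.01 (SD, n = 5, limma adjusted p = 0.565). It was among the 5 genes called in the fit without slides 57 and 58 (3.38, adjusted p = 0.015), which leaves out the slides on which it was low, so that p is no evidence of its own. The sulfur amino acid genes metB2 and cysK had means of -0.97 ± 0.87 and -0.89 ± 0.9997 (SD, n = 5 each; adjusted p = 0.530 and 0.565). For metB2 the slides gave -2.07 on 352, -1.37 on 191, -1.26 on 351, -0.10 on 57 and -0.05 on 58. The gene serA had its lowest value, 0.04, on slide 352 and its highest, 3.29, on slide 57.

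Among genes with a negative mean, dut, coding for dUTPase, had the smallest p, with -0.56 ± 0.18 (SD, n = 5) and a negative value on 5 of 5 slides (adjusted p = 0.202). The anaerobic ribonucleotide reductase activator gene nrdG stood at -0.64 ± 0.33, also below 0 on 5 of 5 slides (adjusted p = 0.274). Neither passed the threshold. Within the arginine list, the antiporter gene arcD1 stood at 6.48 on slide 191 and between -0.78 and 1.52 on the other slides, and arcC3 at 5.03 on slide 191 and between 0.69 and 1.01 on the 3 others that measured it.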
